A study of Mus musculus with 12 samples.

How the data were processed

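RNA was measured in C2i-Myog cells in 4 groups of 3 arrays, named control, Dox, SB and SB+Dox, with replicates numbered 1 to 3 as in the sample titles. Per the submitters' protocol, cells were grown with 10% serum and treated for 48 h from the start of differentiation in 1% horse serum with insulin and transferrin at 10 µg/mL each, with doxycycline at 0.2 µg/mL and SB203580 at 10 µM where given. Total RNA was hybridised to Affymetrix whole-transcript arrays. Per the submitters' processing notes the arrays were summarised with RMA in Affymetrix Expression Console, whose version, like that of the annotation, is not given in the sources used here. The deposited values are log2 RMA signals, 1 per transcript cluster and array. They ran from 0.5 to 13.17 with 0 missing values, and all 12 value columns belonged to a sample.

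Of 35557 transcript clusters, 21789 carried exactly 1 gene symbol, 1621 carried several and 12147 carried none. The clusters with 1 symbol stood for 19938 genes, 999 of them with more than 1 cluster, and 21698 were matched to the gene table by Entrez identifier. Clusters with several symbols or none were left out of the tests and brought back in an alternative. Arrays have no depth, and no signal over background was used here. The precision is set by 3 arrays per group.

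A linear model with 1 mean per group was fitted to the 12 arrays with limma 3.58.1 in R 4.3.3, with statmod 1.5.0 installed for the alternatives. Variances were moderated with eBayes without trend and without the robust option (8 residual and 6.56 prior degrees of freedom). The comparisons were SB against control, SB+Dox against SB, SB+Dox against Dox, Dox against control, SB+Dox against control, and the interaction, which is the doxycycline change with the inhibitor minus that without it. P-values were adjusted within each comparison by the Benjamini-Hochberg method, and a cluster was called at an adjusted p under 0.05 with no minimum fold. SB-lowered and SB-raised clusters for the recovery were those called in SB against control with at least 1.5-fold change. Recovery was the change from SB to SB+Dox divided by the change from SB to control.

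Gene lists were written from general knowledge before the values were examined. They cover sarcomere, calcium handling, neuromuscular junction, fusion, myogenic regulators, muscle metabolism, dystrophin complex, G2/M, DNA replication, immediate early genes, cytokines, the p38 pathway, Notch, extracellular matrix, the insulin-like growth factor axis, TGF-beta and BMP, Wnt, sterol synthesis, ATF4, endoplasmic reticulum stress, heat shock, interferon, aryl hydrocarbon receptor, NRF2, p53, the nuclear respiratory chain, ribosomal proteins, adipocyte, osteoblast and chondrocyte, smooth muscle, and satellite and reserve cell genes. Of 788 memberships in 32 lists 716 were measured. The list of mitochondrially encoded genes had 0 of 13 members measured and was not tested. Each of the other 31 lists was tested in each comparison with camera at a preset correlation of 0.01 on 1 cluster per gene, and again with an estimated correlation and with fry. The preset value takes genes of a list as nearly independent, while the estimated one uses the correlation left between them within groups, and calls that held only under the former are given with both p-values. Members were counted at the adjusted p over all genes and at a p adjusted over the list alone.

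Genes were named by a rule fixed before the values were examined, on the cluster with the highest mean for each gene. Predicted genes, microRNAs, small nucleolar RNAs and olfactory receptors were left out. The rule named Myog, Myod1, Mapk14 and Mapk11, the 8 highest and 8 lowest folds in the first 3 comparisons and 5 and 5 in the others, among called genes whose groups did not overlap, the last not being required for the interaction. It also named up to 4 called members of each list, or the member with the largest change if there was none, and 5 genes of each recovery class.

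The method was tested on simulated data with the spread of these arrays. Of 50 clusters given each fold in SB against control, 72% were recovered at 1.5-fold, 90% at 2-fold and 100% at 4-fold. Among 21589 unchanged clusters 9 were called in that comparison. A list shifted by 0.5 had camera adjusted p = 3.60e-44 with 0 other lists called, and a recovery set at 0.5 was estimated at 0.49. The simulated genes varied independently, while the estimated correlation was 0.68 in the real G2/M list and 0.63 in the ATF4 list. The simulation therefore cannot show how often the preset correlation gives false list calls in these data. Pairing by replicate number was checked by correlating arrays of different groups after removing group means. Same-number arrays of SB and SB+Dox correlated at 0.44, 0.19 and 0.49, each the highest with its own number. The same held for Dox and SB+Dox, at 0.09, 0.28 and 0.15. A block for the number was tried as an alternative.

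Alternatives were the replicate block, repeated quantile normalisation, median centring, leaving out dim clusters under the 25th or 50th percentile, eBayes with trend or robust, array weights, fits over the 6 arrays compared, a minimum fold of 1.5 on calls, all clusters of the table, 1 cluster per gene, other minimum folds for the SB-lowered clusters, recovery on a held-out replicate number, other list tests, and leaving out each array or each number in turn. Other groupings of the arrays were tested by all 10 splits of 3 against 3, and for the interaction by 100 draws of permuted residuals.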

Results

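Gene expression was measured in C2i-Myog cells, a stable line derived from the mouse myoblast line C2C12, in which doxycycline switches on a cDNA for Flag-tagged myogenin (Myog), a transcription factor of muscle differentiation. Cells near confluence were kept for 48 h in medium with 1% horse serum, insulin and transferrin, the usual way to make myoblasts differentiate. The 12 arrays fell into 4 groups of 3. Control cells received no addition, Dox cells received doxycycline at 0.2 µg/mL, SB cells received SB203580, an inhibitor of the α and β forms of p38 MAP kinase, at 10 µM, and SB+Dox cells received both. The control arrays' own label names no differentiation, and they were placed at 48 h of differentiation because the treatment protocol given with every sample describes it. No group received doxycycline without the transgene, so doxycycline and exogenous Myog were measured together.

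Each array gave a log2 expression value for 35557 transcript clusters, of which the 21789 with exactly 1 gene symbol were tested. The array medians lay between 4.86 and 5.06 on the log2 scale. Replicates correlated across clusters with coefficients of 0.992 to 0.996 in control, 0.993 to 0.995 in Dox, 0.989 to 0.994 in SB and 0.994 to 0.996 in SB+Dox. The first principal component held 40.5% of the variance and ordered the groups from SB through SB+Dox and control to Dox, and the second held 17.8%. SB replicate 3 lay apart from SB replicates 1 and 2 on the second component (-8.47 against 20.26 and 11.74) and on the third (-15.15 against 11.43 and 7.72). The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The small number of arrays limits the precision. Adjusted p-values are from limma with Benjamini-Hochberg adjustment, fold changes carry their standard error (SE), and n is 3 arrays per group throughout. For every gene named with a fold change past the test, all 3 arrays of the first group lay beyond all 3 of the second. No background level was measured, so where the lower group lies near or below the array median the true fold may be larger than the one printed.

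Myog itself was the first item examined, because doxycycline was meant to raise it and p38 inhibition acts on the same programme. It measured 9.91 ± 0.26 (log2, SD, n = 3) in control, 10.37 ± 0.05 in Dox, 7.70 ± 0.68 in SB and 8.33 ± 0.30 in SB+Dox. Myog was 4.63-fold lower in SB than in control (log2 change -2.21, SE 0.25, adjusted p = 9.39e-05), with all 3 SB arrays below all 3 control arrays. It remained 4.09-fold lower in SB+Dox than in Dox (adjusted p = 8.86e-05, all 3 arrays) and 2.98-fold lower in SB+Dox than in control (adjusted p = 0.00162, all 3 arrays). The changes with doxycycline did not pass the test: 0.46 without the inhibitor (SE 0.25, adjusted p = 0.467) and 0.64 with it (SE 0.25, adjusted p = 0.157). Without SB replicate 3 the latter was 0.89 with adjusted p = 0.0311 and passed. Positions of the Myog probes relative to the transgene cDNA were not given in the sources used here, so the values may hold the endogenous transcript, the transgene or both.

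Myod1, the determination factor upstream of Myog, measured 10.29 ± 0.26 in control, 10.39 ± 0.17 in Dox, 9.73 ± 0.25 in SB and 9.25 ± 0.14 in SB+Dox (log2, SD, n = 3). It was 2.21-fold lower in SB+Dox than in Dox (log2 change -1.14, SE 0.15, adjusted p = 1.38e-04) and 2.06-fold lower than in control (adjusted p = 6.93e-04), on all 3 arrays each time. In SB against control its change was -0.56 (adjusted p = 0.0356), a call lost without control replicate 1 (adjusted p = 0.127), control replicate 2 (0.165), Dox replicate 1 (0.0507) or SB replicate 1 (0.157). In SB+Dox against SB it was -0.49 (adjusted p = 0.0653), and with the replicate number as a block adjusted p was 0.0174. That change also passed without control replicate 3 (adjusted p = 0.0388) and without SB replicate 1 (adjusted p = 0.031).

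Among genes of the p38 pathway, Map2k6, which encodes an activating kinase of p38, carried the largest rise in SB, from 5.11 ± 0.08 to 7.40 ± 0.27 (log2, SD, n = 3), and stood at 7.42 ± 0.10 in SB+Dox. It was 4.9-fold higher in SB than in control (SE 0.12 on a log2 change of 2.29, adjusted p = 2.34e-07, 3 of 3 arrays). Its levels of 5.11 in control and 4.66 in Dox were not shown to lie above background. Mapk14, the gene of p38α, was 1.46-fold higher in SB+Dox than in Dox (log2 change 0.55, SE 0.09, adjusted p = 0.00115, 3 of 3 arrays). Its change in SB against control was 0.31 with adjusted p = 0.0635, and it passed after quantile normalisation (adjusted p = 0.0145), with dim clusters under the 25th or 50th percentile left out (0.0494 and 0.0297) and with an eBayes trend (0.0434). Mapk11, the gene of p38β, changed by -0.36 in SB against control (adjusted p = 0.0201), a call lost without control replicate 2 (adjusted p = 0.0816), control replicate 3 (0.0663) or SB replicate 2 (0.0995). The 22 measured genes of the pathway had 3 members raised and 5 lowered in SB against control, or 4 and 5 when adjusted over the list alone. Mknk2, a kinase downstream of p38 and ERK, rose by 0.74, while Hspb1, whose protein is phosphorylated downstream of p38, fell by 0.81 (adjusted p = 1.58e-04 and 0.00286, 3 of 3 arrays each). The list had a mean of 0.08, a median of -0.00 and no call (camera adjusted p = 0.905).

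**Figure D1:**
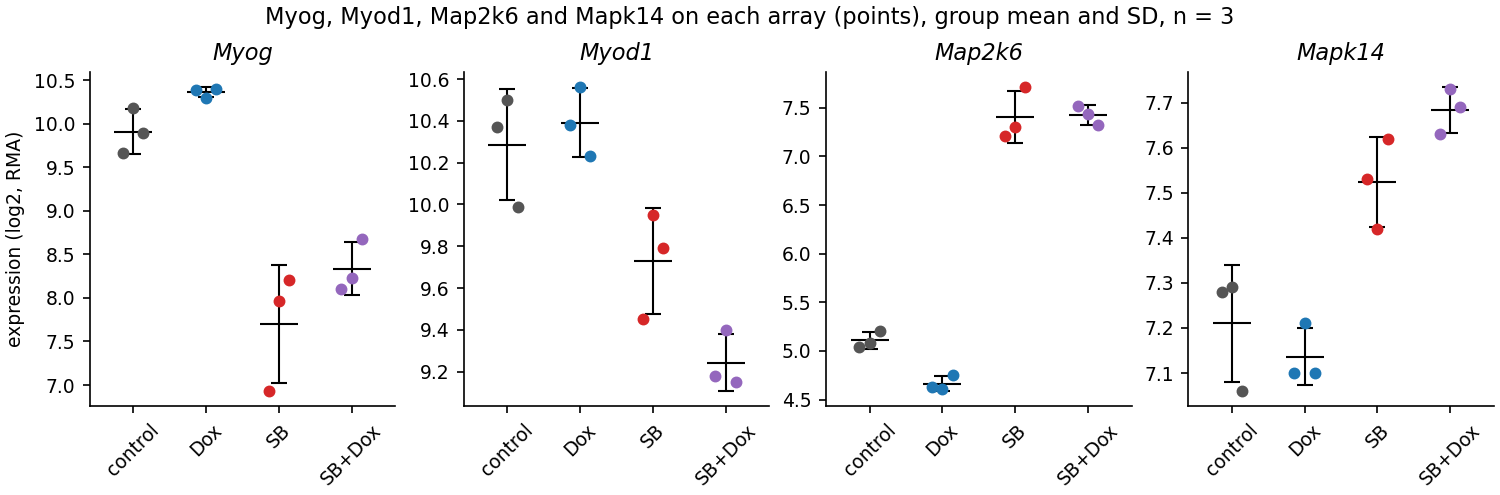
Expression (log2, RMA) of Myog, Myod1, Map2k6 and Mapk14 on each of the 12 arrays, with group mean and SD (n = 3); the y axes differ in range. Map2k6 measured 5.11 in control and 7.40 in SB, and Myog measured 9.91 in control and 7.70 in SB.

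SB against control asks what SB203580 did to differentiating cells that received no doxycycline. Thbs1, which encodes the matrix glycoprotein thrombospondin 1, showed the deepest loss among the named genes, 15.3-fold (log2 change -3.94, SE 0.28, adjusted p = 2.80e-06). Myl4, a myosin light chain of embryonic muscle, was 8.8-fold lower (SE 0.19), Tnc 6.59-fold, Slc40a1 6.06-fold and Col1a1 5.6-fold lower (adjusted p = 8.03e-07, 4.76e-06, 1.50e-04 and 6.10e-05). Beside Map2k6, Gfra1, a receptor for glial cell line-derived neurotrophic factor, was 3.66-fold higher, Tubb3, a tubulin, 3.27-fold higher, and the fatty acid elongase gene Elovl6 2.8-fold higher (adjusted p = 5.09e-06, 0.00177 and 3.66e-05). On each of these genes all 3 SB arrays lay beyond all 3 control arrays. In total 547 clusters were higher and 843 lower among 1390 past the threshold, with 235 higher and 448 lower by at least 1.5-fold. With each array centred on its median the split was 336 higher and 884 lower, with array weights 1142 and 1652, and with every cluster of the table tested 316 and 560. The total was 910 without control replicate 1 and 779 without SB replicate 2. The split was 320 higher and 755 lower without control replicate 3, 277 and 502 without SB replicate 2, and 471 and 541 without SB replicate 1.

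Genes of the contractile apparatus were lower in SB. Of 51 measured sarcomere genes, 21 fell, 1 rose and 29 did not pass the test, or 26 lowered and 1 raised when adjusted over the list alone. Tnnc1, slow troponin C, was 4.27-fold lower, Mybph, a myosin-binding protein, 3.57-fold, and Myom1, an M-band protein, 2.65-fold lower (adjusted p = 2.80e-05, 1.02e-05 and 0.00265). The list had a mean log2 change of -0.61, with all 3 SB arrays below all 3 control arrays (camera adjusted p = 8.66e-18; adjusted p = 0.112 with an estimated correlation). Calcium handling genes had 9 of 25 lowered and 1 raised, or 16 and 3 over the list alone, among them Cacna1s, the pore of the skeletal L-type calcium channel, 3.21-fold lower, and the junctional protein gene Jph2, 3.16-fold lower (adjusted p = 4.29e-04 and 2.29e-05). Their mean was -0.50 on all 3 arrays (camera adjusted p = 7.81e-09; adjusted p = 0.134 with an estimated correlation). Of 17 neuromuscular junction genes 5 fell and 0 rose, or 9 and 0 over the list alone, with the adhesion molecule Ncam1 2.15-fold lower and the agrin co-receptor Lrp4 2.08-fold lower (adjusted p = 2.21e-04 and 0.00635). Their mean was -0.41 on all 3 arrays (camera adjusted p = 9.05e-07; adjusted p = 0.14 with an estimated correlation).

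Both membrane proteins that drive myoblast fusion were lower in SB, Mymk (myomaker) by 3.08-fold and Mymx (myomixer) by 2.69-fold (adjusted p = 6.54e-05 and 5.09e-06, 3 of 3 arrays each). Among the 28 fusion genes 7 fell and 1 rose, the same numbers over the list alone. Their mean was -0.23 on all 3 arrays and their median -0.08 (camera adjusted p = 0.00123, or 0.134 with an estimated correlation). Of 36 myogenic regulators 7 fell and 2 rose, or 9 and 2 over the list alone. Besides Myog these included Bhlhe40, a repressor of the bHLH family, 3.62-fold lower, and Tead4, a DNA-binding partner of YAP and TAZ, 2.62-fold lower (adjusted p = 4.01e-06 and 2.00e-04). The mean was -0.26 on all 3 arrays and the median -0.10 (camera adjusted p = 0.00116, or 0.169 with an estimated correlation). Muscle metabolism genes moved both ways, with 4 of 28 lowered and 3 raised, or 7 and 5 over the list alone. Myoglobin (Mb) was 3.54-fold lower and the muscle cytochrome oxidase subunit Cox6a2 2-fold lower (adjusted p = 3.79e-05 and 0.00239), and the list had no call (mean -0.06, camera adjusted p = 0.666). The dystrophin complex had 1 of 14 genes raised and 1 lowered, or 1 and 3 over the list alone, with no call (mean -0.15, camera adjusted p = 0.191).

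Cell cycle genes were higher in SB. Of 29 G2/M genes 24 rose and 0 fell, and all 29 rose when adjusted over the list alone. The mitotic checkpoint kinase Bub1 was 2.17-fold higher, cyclin A2 (Ccna2) 2-fold and cyclin B2 (Ccnb2) 1.93-fold higher (adjusted p = 0.00554, 0.00285 and 6.48e-04). The list mean rose by 0.68, from 6.12 ± 0.22 to 6.79 ± 0.12 (log2, SD, n = 3), with all 3 SB arrays above all 3 control arrays (camera adjusted p = 1.80e-24; adjusted p = 0.112 with an estimated correlation). Of 31 DNA replication genes 8 rose and 1 fell, or 20 and 1 over the list alone, with a mean of 0.35 on all 3 arrays (camera adjusted p = 3.20e-11; adjusted p = 0.154 with an estimated correlation). Sterol synthesis genes were higher too, with 7 of 18 raised and 0 lowered, or 13 and 0 over the list alone. Dhcr7, the last enzyme of cholesterol synthesis, was 2.17-fold higher and the sterol sensor partner Insig1 1.84-fold higher (adjusted p = 6.11e-05 and 0.00286). Their mean was 0.50 on all 3 arrays (camera adjusted p = 2.38e-11; adjusted p = 0.161 with an estimated correlation).

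Targets of ATF4, the transcription factor of the amino acid response, fell in SB. Of 28 measured members 20 fell and 0 rose, or 25 and 0 over the list alone. Trib3, a pseudokinase, was 2.84-fold lower, the cystine transporter gene Slc7a11 2.82-fold, Nupr1 2.51-fold and the arginine transporter gene Slc7a1 2.34-fold lower (adjusted p = 0.00617, 0.00267, 3.36e-05 and 1.24e-04). The list mean was 8.53 ± 0.23 in control and 7.74 ± 0.15 in SB (log2, SD, n = 3), a change of -0.79 on all 3 arrays (camera adjusted p = 9.60e-28; adjusted p = 0.106 with an estimated correlation). The endoplasmic reticulum stress list had 2 of 19 genes lowered, or 4 over the list alone, with Herpud1 2.17-fold lower (adjusted p = 1.54e-04). Its mean of -0.19 was called (camera adjusted p = 0.00407; adjusted p = 0.542 with an estimated correlation), but not without SB replicate 1 (-0.08, adjusted p = 0.543). Of 17 p53 targets 4 fell and 0 rose, or 9 lowered and 1 raised over the list alone, with Sesn2, shared with the ATF4 list, 2.07-fold lower and the death receptor gene Eda2r 1.94-fold lower (adjusted p = 3.03e-04 and 8.63e-04). Their mean was -0.32 on all 3 arrays (camera adjusted p = 2.47e-06; adjusted p = 0.0396 with an estimated correlation, so the call held).

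Extracellular matrix genes fell as well, with 18 of 37 lowered and 2 raised, or 21 and 2 over the list alone. After Thbs1, Tnc and Col1a1, periostin (Postn) was 3.7-fold lower (adjusted p = 3.66e-05). The matrix mean was -0.63 on all 3 arrays (camera adjusted p = 5.10e-17; adjusted p = 0.0396 with an estimated correlation, so the call held). The small proteoglycan gene Dcn went the other way, 2.95-fold higher (adjusted p = 0.0118), a call lost without control replicate 1 (adjusted p = 0.0546) or control replicate 2 (adjusted p = 0.0594). Of 26 genes of the TGF-beta and BMP pathway 7 fell and 1 rose, or 7 and 2 over the list alone. Skil, a feedback inhibitor of SMAD signalling, was 3.01-fold lower, the inhibitory SMAD gene Smad7 1.96-fold and Ltbp2 1.95-fold lower (adjusted p = 1.06e-05, 4.42e-04 and 7.72e-04). Their mean was -0.25 on all 3 arrays (camera adjusted p = 1.54e-04; adjusted p = 0.0542 with an estimated correlation). Immediate early genes had 6 of 28 lowered and 1 raised, or 8 and 1 over the list alone, with the nuclear receptor Nr4a1 2-fold lower and Klf4 1.71-fold lower (adjusted p = 3.04e-04 and 0.00868). Their mean was -0.26 on all 3 arrays (camera adjusted p = 1.60e-05; adjusted p = 0.112 with an estimated correlation). Smooth muscle genes had 5 of 15 lowered and 0 raised, the same over the list alone, with Actg2, an enteric smooth muscle actin, 4.36-fold and Tagln (transgelin) 3.77-fold lower (adjusted p = 7.21e-06 and 0.00131). Their mean was -0.41 on all 3 arrays (camera adjusted p = 4.04e-05; adjusted p = 0.0396 with an estimated correlation, so the call held).

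SB+Dox against SB asks what doxycycline, given to induce Myog, did in the presence of SB203580. Sorbs2, an adaptor protein of the Z-disc, was 6.56-fold higher (log2 change 2.71, SE 0.21, adjusted p = 1.17e-05), Myl4 5.47-fold (SE 0.19) and cardiac calsequestrin (Casq2) 5.41-fold higher (SE 0.20). The laminin receptor chain Itga6 was 5.33-fold higher and Ankrd2, a stretch-responsive protein of muscle, 5.09-fold higher (adjusted p = 1.17e-05 and 5.67e-04). At the other end, Islr was 2.88-fold lower, the lymphangiogenic growth factor Vegfd 2.49-fold, Kirrel3 2.48-fold and the chemokine receptor Cxcr4 2.42-fold lower (adjusted p = 3.54e-04, 9.00e-05, 5.37e-06 and 6.50e-04). On each of these genes all 3 SB+Dox arrays lay beyond all 3 SB arrays. In total 1550 clusters passed, 959 higher and 591 lower, with 437 and 288 of them at least 1.5-fold. With each array centred on its median the split was 1188 higher and 370 lower, and with array weights 1710 and 1366. The total was 1015 without SB replicate 1, 926 without SB replicate 2, 2521 without SB replicate 3 and 724 without SB+Dox replicate 3.

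Sarcomere genes rose with doxycycline in the presence of the inhibitor. Of 51 members 21 rose and 1 fell, or 28 and 1 over the list alone. Tnnc1 was 4.31-fold higher, the Z-disc protein gene Myoz2 4.33-fold and the M-band protein gene Myom2 3.71-fold higher (adjusted p = 5.83e-05, 0.00186 and 5.57e-05). The list mean was 6.92 ± 0.21 in SB and 7.57 ± 0.12 in SB+Dox, against 7.53 ± 0.14 in control (log2, SD, n = 3). Its change of 0.65 was shared by all 3 arrays (camera adjusted p = 2.56e-18; adjusted p = 0.14 with an estimated correlation). Calcium handling genes had 9 of 25 raised and 0 lowered, or 10 and 1 over the list alone, with the channel subunit gene Cacnb1 2.57-fold and Jph2 2.3-fold higher (adjusted p = 8.92e-05 and 5.17e-04), and a mean of 0.37 on all 3 arrays (camera adjusted p = 1.08e-04; adjusted p = 0.382 with an estimated correlation). Of 17 neuromuscular junction genes 6 rose and 0 fell, or 7 and 0 over the list alone, with the acetylcholine receptor subunit genes Chrnb1 1.96-fold and Chrng 1.89-fold higher (adjusted p = 0.0019 and 0.00241). Their mean was 0.37 on all 3 arrays (camera adjusted p = 3.82e-05; adjusted p = 0.279 with an estimated correlation). Mymk was 3.39-fold higher (adjusted p = 7.93e-05), while the fusion list had 3 of 28 raised and 3 lowered, or 6 and 3 over the list alone, and no call (mean 0.08, median -0.05, camera adjusted p = 0.477).

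The ATF4 targets showed the largest shift of any list in this comparison by mean change. Of 28 members 24 rose and 0 fell, or 26 and 0 over the list alone. Trib3 was 3.51-fold higher, Slc7a11 3.29-fold, the mitochondrial folate enzyme Aldh1l2 3.18-fold and the stress hormone Fgf21 2.9-fold higher (adjusted p = 0.0019, 0.0012, 0.00181 and 1.02e-04). The list mean reached 8.73 ± 0.16 in SB+Dox (log2, SD, n = 3), a rise of 0.99 on all 3 arrays (camera adjusted p = 4.78e-33; adjusted p = 0.14 with an estimated correlation). Genes of the p53 list had 5 of 17 raised and 0 lowered, the same over the list alone, with Plk2 2.6-fold and Gadd45a 2.44-fold higher (adjusted p = 2.71e-05 and 0.00419). Their mean was 0.29 on all 3 arrays (camera adjusted p = 0.00138; adjusted p = 0.14 with an estimated correlation). Immediate early genes had 7 of 28 raised and 0 lowered, or 8 and 1 over the list alone, with the stress-induced factor Atf3 2.96-fold higher (adjusted p = 0.0012). Their mean was 0.22 on all 3 arrays (camera adjusted p = 0.00149; adjusted p = 0.279 with an estimated correlation).

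Both cell cycle lists fell. All 29 G2/M genes were lower, over all genes and over the list alone, with Ccna2 2.39-fold, the kinesin Kif11 2.14-fold and the kinetochore protein Nuf2 2.13-fold lower (adjusted p = 7.62e-04, 0.00208 and 0.00184). The mean change was -0.81 on all 3 arrays (camera adjusted p = 5.27e-27; adjusted p = 0.14 with an estimated correlation). Of 31 DNA replication genes 23 fell and 0 rose, or 30 and 0 over the list alone, with the helicase subunit genes Mcm3 2.32-fold and Mcm5 2.16-fold lower (adjusted p = 7.90e-04 and 0.00123). Their mean was -0.72 on all 3 arrays (camera adjusted p = 9.48e-27; adjusted p = 0.14 with an estimated correlation). Matrix genes had 3 of 37 raised and 6 lowered, or 3 and 11 over the list alone, and no call (mean -0.13, camera adjusted p = 0.0764). Col3a1 was 1.95-fold and Col6a1 1.94-fold lower (adjusted p = 0.001 and 3.42e-04), and Thbs1 was 2.55-fold higher (adjusted p = 0.00841), a call lost without SB+Dox replicate 3 (adjusted p = 0.0523). The TGF-beta and BMP list had 3 of 26 raised and 1 lowered, or 6 and 2 over the list alone, with the receptor gene Tgfbr2 2.02-fold lower (adjusted p = 2.39e-04) and no call (mean -0.01, test direction up, camera adjusted p = 0.961).

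**Figure D2:**
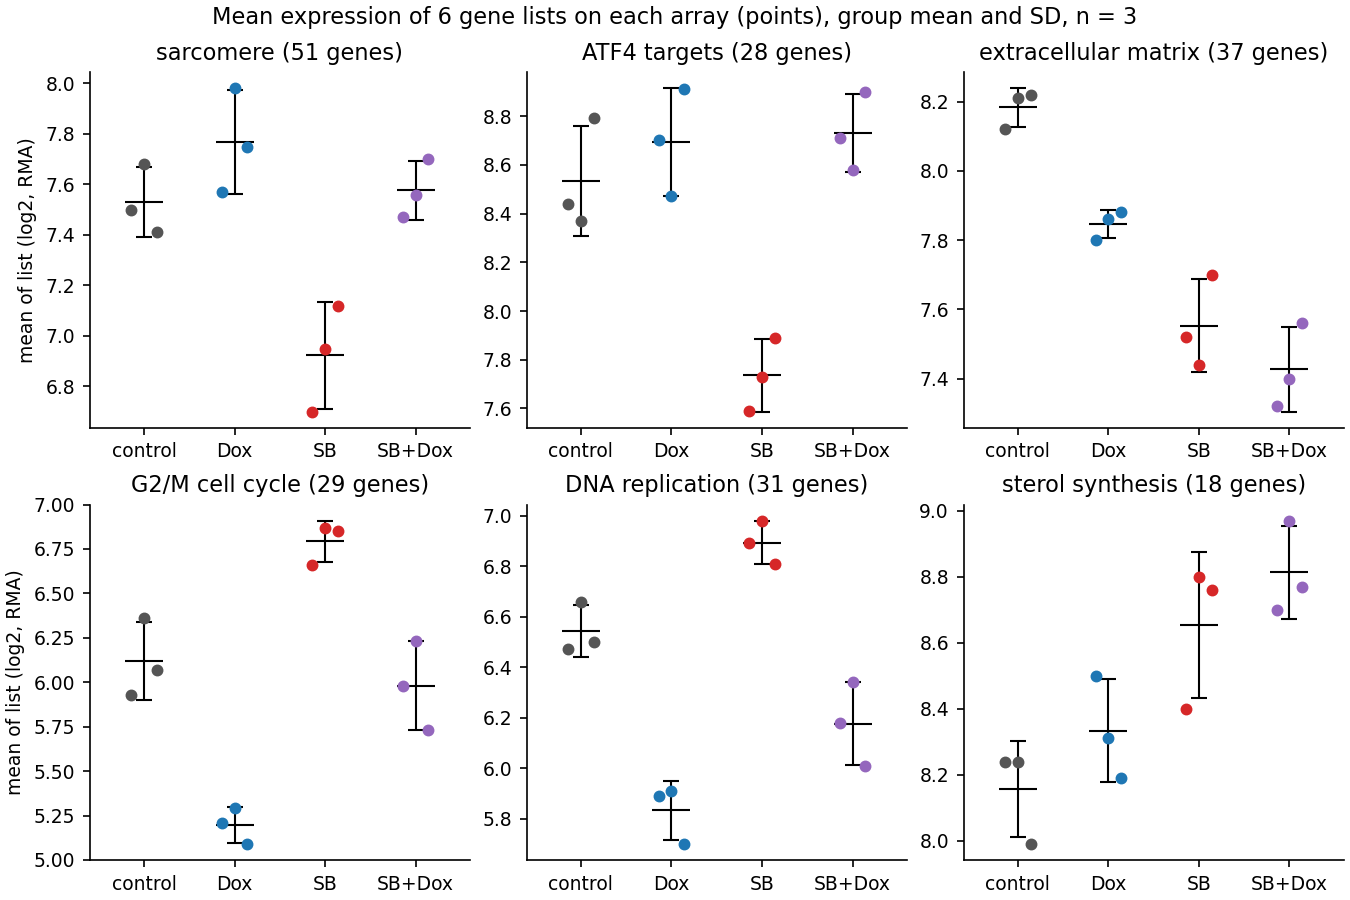
Mean expression (log2, RMA) of 6 gene lists on each of the 12 arrays, with group mean and SD (n = 3); the y axes differ in range. The ATF4 mean was 8.53 in control, 7.74 in SB and 8.73 in SB+Dox, while the matrix mean was 8.18, 7.55 and 7.43.

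Recovery of the SB-lowered genes was measured to ask how much of the loss in SB was reversed in SB+Dox, where doxycycline was given to induce Myog. Of 448 clusters lowered at least 1.5-fold in SB, 196 (43.8%) were raised again by doxycycline. The median recovery was 0.46, where 1 means the control level and 0 the level in SB. By class, 114 clusters (25.4%) were raised and not below the Dox level, 82 (18.3%) were raised and still below it, 166 (37.1%) were not raised and below it, and 86 (19.2%) were neither. Tnnc1, Tagln and Trib3 stood in the first class, Myl4, Tmem182, Sorbs2 and Actg2 in the second, Myog, Tnc, Slc40a1 and Macc1 in the third, and Col1a1 in the last. Of 235 clusters raised at least 1.5-fold in SB, 124 (52.8%) were lowered again, with a median recovery of 0.62. The comparison shares the SB arrays with opposite sign, and in 20 simulations with SB effects and no doxycycline effect the median recovery averaged 0.0315. The simulated SB effects were the observed changes of called clusters, which selection may have enlarged, and genes varied independently. The simulated recovery may therefore understate what the shared arrays give without any doxycycline effect. When clusters were chosen on the other replicate numbers, the median recovery of SB-lowered clusters on the held-out number was 0.38, 0.38 and 0.65, and that of SB-raised clusters 0.32, 0.68 and 0.76.

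By list, recovery was counted over all members called lower in SB against control, with no minimum fold, unlike the 448 clusters above. Among such sarcomere genes 15 of 21 were raised by doxycycline, and among ATF4 targets 18 of 20. Calcium handling genes had 6 of 9 raised, neuromuscular junction genes 4 of 5, p53 targets 4 of 4 and smooth muscle genes 3 of 5. Fusion genes had 3 of 7 raised, with Mymk among them and Mymx not, and myogenic regulators had 3 of 7. Of the 18 matrix genes called lower in SB, Thbs1 was the 1 raised, and that call was lost without SB+Dox replicate 3 (adjusted p = 0.0523).

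**Figure D3:**
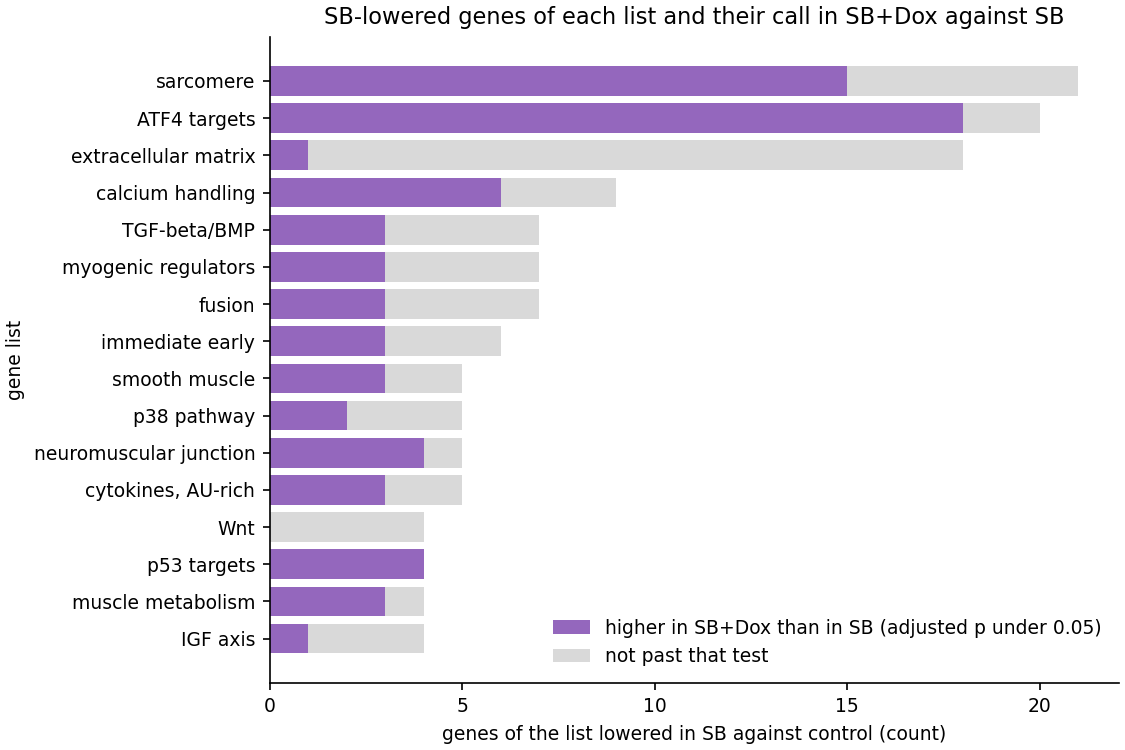
Number of genes of each list called lower in SB against control at any fold (bar length, count), divided into those higher in SB+Dox than in SB at adjusted p under 0.05 (purple) and those not past that test (grey), for lists with 4 or more such genes. The ATF4 list had 18 of 20 raised and the matrix list 1 of 18.

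SB+Dox against Dox asks what SB203580 did in the presence of doxycycline. It shares no array with SB against control. Ctrb1, a chymotrypsinogen gene, was 25-fold lower (log2 change -4.64, SE 0.21, adjusted p = 1.46e-08), falling from 10.42 ± 0.25 in Dox to 5.78 ± 0.15 in SB+Dox (log2, SD, n = 3). The annexin gene Anxa8 was 24.3-fold lower, R3hdml 13.2-fold, the serotonin receptor gene Htr2b 11.4-fold, Thbs1 10.9-fold and the desmoglein gene Dsg3 9.42-fold lower (adjusted p = 4.76e-07, 8.04e-07, 2.75e-07, 2.00e-06 and 1.81e-07). Dcn was 8.91-fold higher, Map2k6 6.78-fold, Gfra1 6.23-fold, the guidance cue Sema3c 5.72-fold and the actin-capping protein gene Tmod1 5.59-fold higher (adjusted p = 2.79e-05, 1.46e-08, 9.84e-08, 7.09e-07 and 1.72e-07). All 3 SB+Dox arrays lay beyond all 3 Dox arrays for each of these genes. In total 1518 clusters were higher and 747 lower among 2265 past the threshold, of which 714 and 385 changed at least 1.5-fold.

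Mymx was 3.85-fold lower, Bhlhe40 3.37-fold and Mb 4.99-fold lower (adjusted p = 1.17e-07, 1.55e-06 and 1.56e-06), while the muscle glycogen phosphorylase gene Pygm was 3.71-fold, the coactivator gene Ppargc1a 2.33-fold and Pgam2 2.29-fold higher (adjusted p = 4.73e-06, 0.00114 and 0.0052). Muscle metabolism genes had 10 of 28 raised and 2 lowered, or 10 and 3 over the list alone, and no call (mean 0.15, median -0.05, camera adjusted p = 0.182). Of 51 sarcomere genes 9 fell and 1 rose, the same over the list alone, with Myl4 3.15-fold and Mybph 2.33-fold lower (adjusted p = 4.54e-05 and 1.32e-04). The sarcomere mean was -0.19, and its 3 arrays overlapped those of Dox (camera adjusted p = 0.00685; adjusted p = 0.66 with an estimated correlation). That call was lost without Dox replicate 2 (mean -0.09, adjusted p = 0.143) or SB+Dox replicate 1 (mean -0.14, adjusted p = 0.055). Calcium handling genes had 6 of 25 lowered and 1 raised, or 7 and 3 over the list alone, with a mean of -0.16 and overlapping arrays (camera adjusted p = 0.0275; adjusted p = 0.642 with an estimated correlation), a call lost without Dox replicate 2 (0.0967), SB+Dox replicate 1 (0.133) or SB+Dox replicate 2 (0.0645). The fusion list, with 8 of 28 lowered and 3 raised, or 10 and 4 over the list alone, had a mean of -0.21 on all 3 arrays (camera adjusted p = 0.0157; adjusted p = 0.45 with an estimated correlation), and its call was lost without Dox replicate 2 (adjusted p = 0.0514) or SB+Dox replicate 1 (adjusted p = 0.0534). Of 28 ATF4 targets 4 rose and 3 fell, the same over the list alone, with a mean of 0.03 and no call (camera adjusted p = 0.93).

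G2/M genes were higher in SB+Dox than in Dox, with 24 of 29 raised and 0 lowered, or 28 and 0 over the list alone. Bub1 was 2.64-fold, Top2a 2.5-fold and Ccna2 2.46-fold higher (adjusted p = 5.71e-04, 2.52e-04 and 1.94e-04). The mean was 0.78 on all 3 arrays (camera adjusted p = 7.00e-23; adjusted p = 0.358 with an estimated correlation). DNA replication genes had 16 of 31 raised and 2 lowered, or 18 and 2 over the list alone, with Uhrf1 1.91-fold higher and the ribonucleotide reductase gene Rrm2 2.93-fold lower (adjusted p = 0.00137 and 1.82e-05). Their mean was 0.34 on all 3 arrays (camera adjusted p = 4.57e-09; adjusted p = 0.45 with an estimated correlation). Matrix genes had 12 of 37 lowered and 2 raised, or 14 and 2 over the list alone, with Postn 5.39-fold and Tnc 4.82-fold lower (adjusted p = 1.40e-06 and 6.05e-06). Their mean was -0.42 on all 3 arrays and their median -0.17 (camera adjusted p = 6.37e-06, or 0.392 with an estimated correlation). The TGF-beta and BMP list had 7 of 26 lowered and 1 raised, or 9 and 2 over the list alone. Ltbp2 was 4.94-fold lower and the activin antagonist Fst 3.15-fold lower (adjusted p = 1.68e-07 and 1.40e-05). The list mean was -0.24 on all 3 arrays and the median -0.05 (camera adjusted p = 0.0157, or 0.358 with an estimated correlation).

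Sterol synthesis genes were again higher, with 7 of 18 raised and 0 lowered, or 10 and 0 over the list alone. Dhcr7 was 3.66-fold and Lss, lanosterol synthase, 2.11-fold higher (adjusted p = 2.12e-07 and 5.49e-04). The sterol mean was 0.48 on all 3 arrays (camera adjusted p = 1.59e-07; adjusted p = 0.498 with an estimated correlation). Nuclear respiratory chain genes had 5 of 29 raised and 0 lowered, or 11 and 0 over the list alone, with Cyc1 1.48-fold and Sdha 1.38-fold higher (adjusted p = 0.00743 and 0.0073). Their mean was 0.23 on all 3 arrays (camera adjusted p = 7.42e-06; adjusted p = 0.532 with an estimated correlation). The p38 pathway list had 7 of 22 raised and 1 lowered, or 8 and 1 over the list alone, with Mknk2 2.63-fold higher (adjusted p = 2.12e-07). Its mean was 0.25 on all 3 arrays and its median 0.09 (camera adjusted p = 0.0203, or 0.358 with an estimated correlation).

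Dox against control asks what doxycycline, given to induce Myog, did without the inhibitor, and the submitters' protocol calls this group the control for doxycycline. R3hdml was 9.29-fold higher (log2 change 3.22, SE 0.28, adjusted p = 2.16e-05), Anxa8 6.59-fold, the adipokine gene C1qtnf3 5.57-fold, Ctrb1 5.44-fold and Dsg3 5.01-fold higher (adjusted p = 1.69e-04, 1.37e-04, 2.16e-05 and 2.16e-05). Tecrl was 7.48-fold lower, Dcn 6.26-fold, Sema3c 4.83-fold, Col1a1 4.64-fold and Aspn 4.41-fold lower (adjusted p = 1.99e-04, 3.00e-04, 1.35e-05, 1.87e-04 and 9.31e-05). On all of them the 3 Dox arrays lay beyond the 3 control arrays. In total 1156 clusters passed, 311 higher and 845 lower, with 173 and 496 at least 1.5-fold. With array weights 554 were higher and 1277 lower. The total was 769 without control replicate 1 and 744 without Dox replicate 3. The split was 178 higher and 616 lower without Dox replicate 2, and 192 and 786 without control replicate 3.

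G2/M genes fell with doxycycline alone, with 27 of 29 lowered and 0 raised, and all 29 lowered over the list alone. Top2a was 3.16-fold, Ccna2 2.93-fold and Kif11 2.74-fold lower (adjusted p = 1.23e-04, 1.35e-04 and 2.41e-04), and the mean was -0.92 on all 3 arrays (camera adjusted p = 1.27e-38; adjusted p = 0.153 with an estimated correlation). DNA replication genes had 25 of 31 lowered and 1 raised, or 28 and 1 over the list alone, with Mcm3 2.98-fold and the methylation factor Uhrf1 2.53-fold lower (adjusted p = 1.02e-04 and 1.88e-04). Their mean was -0.71 on all 3 arrays (camera adjusted p = 2.98e-32; adjusted p = 0.151 with an estimated correlation). Of 51 sarcomere genes 7 rose and 2 fell, or 17 and 2 over the list alone. Myoz2 was 3.41-fold and the leiomodin gene Lmod2 2.06-fold higher, and Mybpc1 2.25-fold and Tmod1 2.22-fold lower (adjusted p = 0.00575, 0.00153, 0.0016 and 3.64e-04). The mean was 0.24, with overlapping arrays (camera adjusted p = 2.15e-05; adjusted p = 0.657 with an estimated correlation). Matrix genes had 12 of 37 lowered and 3 raised, or 17 and 6 over the list alone, with Col3a1 3.59-fold lower (adjusted p = 9.20e-06) and a mean of -0.34 on all 3 arrays (camera adjusted p = 5.67e-05; adjusted p = 0.422 with an estimated correlation). The insulin-like growth factor axis had 4 of 17 lowered and 1 raised, or 5 and 1 over the list alone, with the receptor substrate gene Irs1 3.09-fold and Igfbp5 2.05-fold lower (adjusted p = 2.16e-05 and 0.00114). Its mean was -0.31 on all 3 arrays (camera adjusted p = 0.00233; adjusted p = 0.217 with an estimated correlation).

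Among the ATF4 targets 0 of 28 passed in Dox against control, over all genes or over the list alone, by limma, where 3191 clusters had an unadjusted p under 0.05. The list mean was 0.16 with overlapping arrays (camera adjusted p = 0.00233; adjusted p = 0.72 with an estimated correlation), and the call was lost without control replicate 2 (0.08, adjusted p = 0.0993) or Dox replicate 3 (0.06, adjusted p = 0.24). Satellite and reserve cell genes had 5 of 20 lowered and 1 raised, or 7 and 2 over the list alone. Myf5, a determination factor of satellite cells, was 2.23-fold lower and the stem cell antigen Cd34 2.07-fold lower (adjusted p = 2.35e-04 and 0.00141). The list mean was -0.22 on all 3 arrays and the median -0.06 (camera adjusted p = 0.0136, or 0.422 with an estimated correlation). That call was lost without Dox replicate 3 (-0.17, adjusted p = 0.0863). Mymx was 1.82-fold higher (adjusted p = 3.12e-04), while the fusion list had 5 of 28 raised and 3 lowered, or 6 and 4 over the list alone, and no call (mean 0.06, camera adjusted p = 0.646).

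SB+Dox against control asks what remained different from control when both compounds were given. Col1a1 was 7.55-fold lower (log2 change -2.92, SE 0.27, adjusted p = 1.97e-05), the proteoglycan versican (Vcan) 6.78-fold, Tnc 6.54-fold, Thbs1 6.01-fold and Frmpd1 5.6-fold lower. Map2k6 was 4.97-fold higher, the inositol phosphatase gene Inpp5j 4.67-fold, the keratin gene Krt80 4.27-fold and Ankrd2 3.59-fold higher (adjusted p = 1.03e-07, 1.77e-06, 5.62e-05 and 0.00262). Each of these genes had all 3 SB+Dox arrays beyond all 3 control arrays. In total 618 clusters were higher and 528 lower among 1146 past the threshold, with 281 and 288 at least 1.5-fold. Which direction was more frequent depended on the setting, with 615 higher and 618 lower after quantile normalisation, 349 and 435 without control replicate 3, and 322 and 375 without SB+Dox replicate 3. With array weights 1000 were higher and 935 lower, and with every cluster of the table tested 353 and 343. The total was 747 without control replicate 1, 644 without SB+Dox replicate 2 and 697 without SB+Dox replicate 3.

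Matrix genes were lower, with 21 of 37 lowered and 1 raised, or 25 and 2 over the list alone, and the collagen cross-linking enzyme gene Lox 3.65-fold lower (adjusted p = 2.46e-05). Their mean was -0.76 on all 3 arrays (camera adjusted p = 1.47e-23; adjusted p = 0.0408 with an estimated correlation, so the call held). Sterol synthesis genes were higher, with 11 of 18 raised and 0 lowered, or 16 and 0 over the list alone, with Dhcr7 2.91-fold and Lss 2.58-fold higher (adjusted p = 4.49e-06 and 2.00e-04). Their mean was 0.66 on all 3 arrays (camera adjusted p = 1.48e-17; adjusted p = 0.17 with an estimated correlation). Sarcomere genes had 4 of 51 raised and 6 lowered, or 7 and 6 over the list alone, with Tmod1 2.52-fold higher (adjusted p = 1.33e-04) and no call (mean 0.04, camera adjusted p = 0.404). DNA replication genes had 8 of 31 lowered and 0 raised, or 14 and 0 over the list alone, with Rfc3, a clamp loader subunit, 1.89-fold lower (adjusted p = 5.36e-04) and a mean of -0.37 on all 3 arrays (camera adjusted p = 4.38e-11; adjusted p = 0.299 with an estimated correlation). The TGF-beta and BMP list had 6 of 26 lowered and 0 raised, or 10 and 0 over the list alone, with a mean of -0.26 on all 3 arrays (camera adjusted p = 1.22e-04; adjusted p = 0.0823 with an estimated correlation). Nuclear respiratory chain genes had 3 of 29 raised and 0 lowered, or 5 and 0 over the list alone, with a mean of 0.22 on all 3 arrays (camera adjusted p = 5.15e-08; adjusted p = 0.401 with an estimated correlation).

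The interaction asks whether the effect of doxycycline differed with and without SB203580, which is the same as asking whether the inhibitor acted differently with and without doxycycline. Positive values mean that doxycycline raised a gene more, or lowered it less, when the inhibitor was present. Tmod1 had an interaction of 1.83 (log2, SE 0.22, adjusted p = 0.00253), since doxycycline lowered it in the absence of the inhibitor, from 8.86 ± 0.31 to 7.71 ± 0.30, and its level was 9.51 ± 0.03 in SB and 10.19 ± 0.08 in SB+Dox (log2, SD, n = 3). Ctrb1 had -2.52 (SE 0.30, adjusted p = 0.00253), R3hdml -3.07 (SE 0.39, adjusted p = 0.00381) and the matrix regulator Adamtsl2 -2.06 (SE 0.28, adjusted p = 0.00673), each induced by doxycycline without the inhibitor and near its SB level with both. Pygm had 1.56 and Ltbp2 -1.34 (adjusted p = 0.0122 and 0.0101). In total 195 clusters passed, 158 positive and 37 negative, with 59 and 25 after quantile normalisation and 6 in all when every cluster of the table was tested. With the replicate number as a block the split was 356 positive and 65 negative, and with array weights 546 and 132. The total was 47 without control replicate 1, 115 and 99 without control replicates 2 and 3, 116, 56 and 123 without Dox replicates 1, 2 and 3, and 56, 27 and 352 without SB replicates 1, 2 and 3. Without SB+Dox replicates 1, 2 and 3 it was 93, 93 and 28.

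Of the 28 ATF4 targets 7 had a positive interaction and 0 a negative one, or 24 and 0 over the list alone. Chac1, a glutathione-degrading enzyme of the ATF4 response, had an interaction of 1.30 (SE 0.18, adjusted p = 0.00695). The calls of Asns and Psat1 were each lost for 9 of the 12 arrays left out singly, the exceptions being control replicate 2, Dox replicate 3 and SB replicate 3 for Asns (adjusted p from 0.0603 to 0.108 where lost) and Dox replicates 1 and 3 and SB replicate 3 for Psat1 (0.0548 to 0.104). The list mean was 0.83 (camera adjusted p = 9.89e-26; adjusted p = 0.193 with an estimated correlation). Sarcomere genes had 4 of 51 positive and 0 negative, or 13 and 0 over the list alone, and a mean of 0.42 (camera adjusted p = 1.69e-07; adjusted p = 0.425 with an estimated correlation). Of the 4, Tmod1 kept its call whichever array was left out. Tnnc1 lost it without SB replicate 2 (adjusted p = 0.0549) or SB+Dox replicate 3 (0.0547), and Myl4 without control replicate 3 (0.0542), SB replicate 1 (0.0581), SB replicate 2 (0.0625) or SB+Dox replicate 3 (0.0611). Myom2 lost it without control replicates 1, 2 or 3 (0.0553, 0.0544 and 0.0521), Dox replicates 1 or 2 (0.0567 and 0.0568), SB replicate 2 (0.0761) or SB+Dox replicate 3 (0.0713). G2/M genes had 0 of 29 past the test in either direction by limma, over all genes or the list alone, where 2490 clusters had an unadjusted p under 0.05, and a mean of 0.11 (camera adjusted p = 0.208), so their fall with doxycycline was not shown to differ with the inhibitor. Sterol genes likewise had 0 of 18 past the test, or 1 raised over the list alone, and a mean of -0.02 (camera adjusted p = 0.889). Matrix genes had 2 positive and 2 negative among 37, or 7 and 2 over the list alone, with a mean of 0.21 (camera adjusted p = 0.0194; adjusted p = 0.591 with an estimated correlation), a call lost without SB replicate 1 (adjusted p = 0.0702), SB replicate 2 (0.17) or SB+Dox replicate 3 (0.199).

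Across clusters, the SB effect without doxycycline correlated with the SB effect with it at r = 0.56 and rho = 0.33, and the doxycycline effect without the inhibitor with that in its presence at r = 0.44 and rho = 0.28. Neither pair shares an array, and 3 pairs of comparisons were correlated in all. Same-number arrays correlated at 0.44, 0.19 and 0.49 between SB and SB+Dox and at 0.01, 0.18 and 0.39 between control and Dox, so without any shared change the SB effects may correlate above 0 and their lists share more clusters than independent ones. Genes are not independent replicates, so no p-value is given. Of 547 clusters raised in SB against control, 415 were also raised in SB+Dox against Dox, where independent lists would share 38.1. Of 843 lowered ones, 357 were lowered in both, against 28.9 for independent lists. For doxycycline 122 clusters were raised and 331 lowered in both comparisons, against 13.7 and 22.9. SB against control and SB+Dox against SB share the SB arrays with opposite sign and correlated at r = -0.56 (rho = -0.53). Simulated data gave a mean r of -0.50 with no effect at all, and of -0.28 with SB effects but no doxycycline effect. The covariance of these comparisons was -0.0363, against -0.00897 simulated with no effect. Between them, 350 clusters were lowered by SB and raised by doxycycline, where independent lists would share 37.1, and 221 were raised and then lowered, against 14.8. Splitting the 3 shared arrays would leave fewer than 2 on a side, so part of the excess may come from the sharing.

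**Figure D4:**
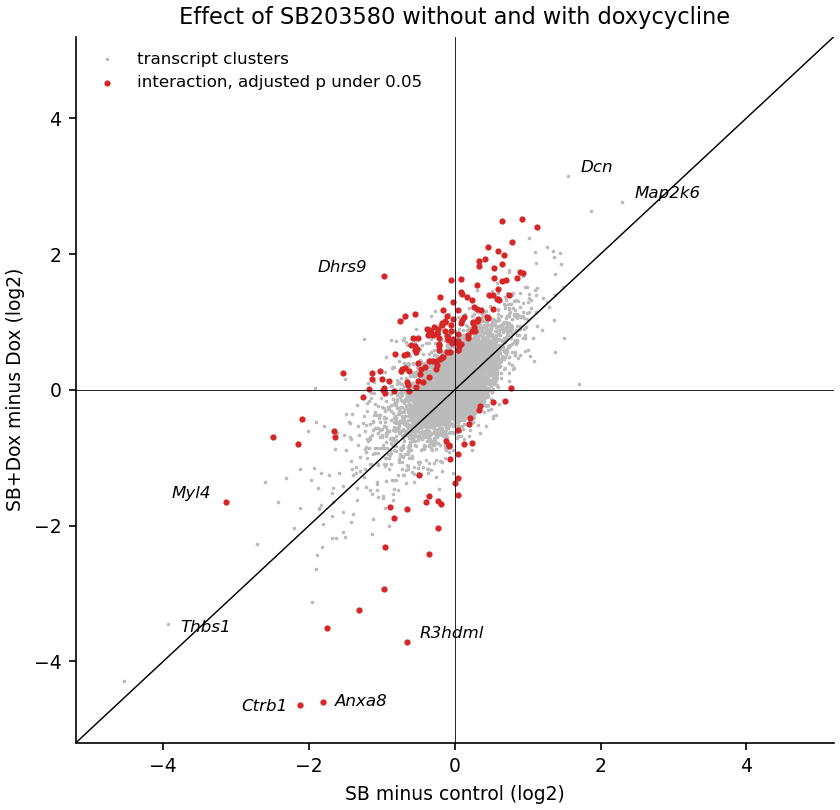
Change with SB203580 without doxycycline (x axis, SB minus control, log2) and with it (y axis, SB+Dox minus Dox, log2) for each named transcript cluster (points); red points passed the interaction test and the diagonal marks equal changes. The correlation was r = 0.56, and Ctrb1, Anxa8 and R3hdml lie far below the diagonal.

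Several lists moved little or lost their calls. In SB against control, 0 of 23 interferon-stimulated genes, 0 of 29 nuclear respiratory chain genes, 0 of 13 adipocyte markers and 0 of 12 osteoblast and chondrocyte markers passed in limma, over all genes or over each list alone, where 3778 clusters had an unadjusted p under 0.05. These lists had mean changes of 0.04, 0.06, 0.01 and 0.07 (camera adjusted p = 0.666, 0.309, 0.905 and 0.487). Their mean levels in control were 4.76, 9.05, 4.76 and 4.90 (log2). The interferon, adipocyte and osteoblast and chondrocyte lists thus lay near or below the array medians. A fall in them could hardly have been seen, unlike in the respiratory chain list. Aryl hydrocarbon receptor targets had 1 of 8 raised, or 2 over the list alone, and no call (mean 0.05, camera adjusted p = 0.666). Cytosolic heat shock genes had 1 of 15 raised and 3 lowered, or 1 and 4 over the list alone (mean -0.07, median 0.06, camera adjusted p = 0.523). Ribosomal protein genes had 0 of 22 past the test and a mean of 0.09 that was called (camera adjusted p = 0.0241; adjusted p = 0.62 with an estimated correlation), a call lost without control replicate 1 (0.09, adjusted p = 0.117) or SB replicate 3 (0.07, adjusted p = 0.379). Cytokines and other short-lived inflammatory transcripts had 5 of 29 lowered and 0 raised, or 5 and 1 over the list alone, with Ptgs2, the inducible cyclooxygenase, 3.91-fold lower (adjusted p = 5.72e-05). Their mean was -0.18 on all 3 arrays and their median -0.05 (camera adjusted p = 0.0178, or 0.219 with an estimated correlation). That call was lost without control replicate 3 (-0.14, adjusted p = 0.14) or SB replicate 3 (-0.15, adjusted p = 0.0936).

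Signalling lists without a call in SB against control held single genes that changed. The Notch list had 2 of 18 raised and 1 lowered, or 3 and 3 over the list alone, with the ligase gene Dtx4 rising by 0.68 and the target gene Hes1 falling by 0.83 (adjusted p = 0.00714 and 0.00233), and a mean of 0.03 (camera adjusted p = 0.679). The Wnt list had 4 of 25 lowered and 1 raised, or 6 and 1 over the list alone, with the receptor gene Fzd2 1.8-fold and Ccn4 1.79-fold lower (adjusted p = 0.00249 and 5.74e-04), a mean of -0.06 and a median of 0.05 (camera adjusted p = 0.437). The insulin-like growth factor axis had 4 of 17 lowered and 1 raised, the same over the list alone, with the binding protein gene Igfbp2 falling by 0.80 and Igf1 itself rising by 0.58 (adjusted p = 0.002 and 0.00252), and a mean of -0.09 (camera adjusted p = 0.246). Targets of NRF2 had 1 of 16 raised and 2 lowered, or 1 and 3 over the list alone, with the glutathione transferase gene Gstm1 rising by 0.75 (adjusted p = 0.0025), a mean of -0.05 and a median of 0.03 (camera adjusted p = 0.995). Satellite and reserve cell genes had 2 of 20 raised and 2 lowered, or 2 and 3 over the list alone, with Cd34 2.72-fold higher (adjusted p = 1.31e-04) and a mean of -0.00 (camera adjusted p = 0.666).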

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

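The tests on Myog probe position and on doxycycline by itself for the ATF4 list were chosen only after the results were seen. The ATF4 pattern and the clusters, lists and genes named after the 3 patterns drew attention by a difference between the doxycycline effects with and without SB203580, tested as the interaction. The Myog and cell cycle patterns showed no such difference past the test (Myog 0.18, limma adjusted p = 0.88; G2/M list 0.11, camera adjusted p = 0.208; DNA replication list -0.01, camera adjusted p = 0.859) and were weighed because of their place in the design.

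The first pattern weighed was the small Myog change with doxycycline, 0.64 in SB+Dox against SB (adjusted p = 0.157, limma). A swap of SB and SB+Dox arrays is argued against by a score of the clusters called in Dox against control, on which the lowest SB+Dox array lay 0.66 above the highest SB array. A swap of control and Dox arrays is argued against by the reverse score, with a gap of 0.63. Each score takes the labels of the other pair of groups as right, so a swap of both pairs at once was not tested. Probes outside the transgene cDNA remain open, since the larger of the Myog changes was 0.64 and probe positions were not given in the sources used here. A low level of transgene expression was not tested and may be the cause as well.

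The second pattern was the ATF4 list, lower in SB and higher again in SB+Dox, with an interaction of 0.83 (SE 0.22; camera adjusted p = 9.89e-26; adjusted p = 0.193 with an estimated correlation, and 0.0408 with fry). For the fall in SB, array brightness was tested by repeated quantile normalisation, which left a mean of -0.78 in SB against control. The RMA values were already normalised, with array medians between 4.86 and 5.06, so the repeat could hardly have removed the fall and decides little. A single SB array is argued against by a smallest mean of -0.72 when any of them was left out. These tests covered only the fall in SB, not the rise in SB+Dox or the interaction. With doxycycline the list mean changed by 0.16 without the inhibitor, against 0.99 with it. The bound set for this test, that the change without the inhibitor lie below 0.5 times that with it by more than 2 standard errors, was chosen after these values were seen and was missed (difference 0.33, SE 0.19), so this explanation stays open. An effect of exogenous Myog that depends on p38α/β may be a biological explanation, and it cannot be told apart from doxycycline acting in inhibited cells, as no array had doxycycline without the transgene.

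The third pattern was the cell cycle lists, higher with SB203580 and lower with doxycycline. Their G2/M calls were lost with an estimated correlation (camera adjusted p = 0.112 in SB against control and 0.153 in Dox against control). With fry both G2/M calls held (adjusted p = 0.00696 in SB against control and 0.00429 in Dox against control). Repeated quantile normalisation, the test for array brightness, left G2/M means of 0.69 in SB against control and -0.91 in Dox against control. On RMA values, which were already normalised, it could hardly have removed these changes and decides little. A single array is argued against by smallest means of 0.58 and -0.80 when any array was left out. Whether doxycycline itself or exogenous Myog lowered the G2/M list, by a mean change of -0.92 in Dox against control, stays open, since no array measured doxycycline in cells without the transgene.

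The interaction passed the test for 195 clusters. Of 100 draws of permuted residuals, 1, the real one, gave as many, with 59 as the highest other. This argues against chance only for arrays taken as exchangeable. The draws ignored that same-number SB and SB+Dox arrays correlated (0.44, 0.19 and 0.49). With the replicate block 421 clusters passed, a fit for which no draws were made. The number was 27 without SB replicate 2 and 28 without SB+Dox replicate 3, 47 without control replicate 1, 56 without Dox replicate 2 or SB replicate 1, 93 without SB+Dox replicate 1 or 2, 99 and 115 without control replicates 3 and 2, 116 and 123 without Dox replicates 1 and 3, and 352 without SB replicate 3. For the pairwise comparisons the 10 splits of 6 arrays are too few for a share under 0.05, and 1 split, the real one, gave as many each time. The real and highest other numbers were 1390 and 1 for SB against control, 1550 and 3 for SB+Dox against SB, 2265 and 0 for SB+Dox against Dox, 1156 and 1 for Dox against control, and 1146 and 0 for SB+Dox against control. Every other split mixed arrays of both real groups, so the real difference widened the spread within groups. Their low numbers therefore do not measure what unaffected arrays would give.

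Other lists called in the interaction with camera at the preset correlation, all of them lost with an estimated correlation, had positive means. With fry the calls of the p38 pathway (adjusted p = 0.0277) and smooth muscle (0.0342) held, and those of the rest, all muscle lists below among them, were lost. Muscle lists had means of 0.42 for sarcomere, 0.34 for calcium handling, 0.25 for the neuromuscular junction, 0.21 for muscle metabolism and 0.23 for the dystrophin complex. The neuromuscular junction call was lost without control replicate 2 (camera adjusted p = 0.119), SB replicate 1 (0.122) or SB+Dox replicate 3 (0.0595), and the dystrophin complex call without SB replicate 1 (0.0708) or SB+Dox replicate 3 (0.0688). The muscle metabolism call was lost without control replicate 2 (0.162), Dox replicate 1 (0.0505), Dox replicate 3 (0.0978), SB replicate 1 (0.342) or SB+Dox replicate 3 (0.087). Signalling and matrix lists had 0.34 for immediate early genes, 0.17 for the p38 pathway, 0.21 for extracellular matrix and 0.26 for the insulin-like growth factor axis. The matrix call was lost without SB replicate 1 (0.0702), SB replicate 2 (0.17) or SB+Dox replicate 3 (0.199). The remaining lists had 0.27 for NRF2 targets, 0.19 for p53 targets, 0.16 for the nuclear respiratory chain and 0.29 for smooth muscle. Without SB replicate 1 the calls of NRF2 targets (0.0702), the respiratory chain (0.0856) and p53 targets (0.103) were lost, the last also without control replicate 1 (0.0525), control replicate 2 (0.0617) or SB+Dox replicate 3 (0.0582).

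Named genes with the highest interactions were Dhrs9 at 2.64, Tmod1 at 1.83, Aspn at 1.80, Col1a1 at 1.78 and Atf3 at 1.76. The lowest were Rrad at -1.95, Adamtsl2 at -2.06, Ctrb1 at -2.52, Anxa8 at -2.79 and R3hdml at -3.07. Without SB replicate 2 the calls of Dhrs9 (adjusted p = 0.0855, limma), Aspn (0.0771), Col1a1 (0.133), Atf3 (0.0866), Rrad (0.0625) and Anxa8 (0.0605) were lost. Over all arrays left out in turn, the call was lost for 7 of them for Dhrs9, 5 for Aspn, 9 for Col1a1, 8 for Atf3, 3 for Rrad and 2 for Anxa8, while Tmod1, Adamtsl2, Ctrb1 and R3hdml kept it for each of the 12.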

How the results depend on the processing

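The alternatives were chosen before the data were examined, and the cause of each shift was not tested unless stated. Of 228 changes of named genes, 163 kept their direction and their side of the threshold under every alternative run, 60 lost the call under at least 1, 3 gained it and 2 changed sign. Of 82 list calls 4 held throughout, 78 were lost with an estimated correlation and 0 changed sign. The estimate uses the correlation between genes that the preset leaves out, but this alone does not account for every loss. The smooth muscle list in the interaction had an estimated correlation of 0.00, and its camera adjusted p still went from 0.00314 to 0.146. With an estimated correlation 3 lists were called in SB against control, 1 in SB+Dox against control, and 0 in SB+Dox against SB, 0 in SB+Dox against Dox, 0 in Dox against control and 0 in the interaction. With fry 49 of the 82 list calls held and 33 were lost, with 7 lists called in SB+Dox against SB, 5 in Dox against control and 3 in the interaction. With the replicate block 421 clusters passed the interaction test and 51.5% of the SB-lowered clusters were raised by doxycycline. The labels do not say what same-number arrays share for any pair of groups. Outside the pair SB and SB+Dox, same-number arrays correlated from -0.14 to 0.39. Dox arrays correlated with SB+Dox arrays at 0.09, 0.28 and 0.15, each the highest with its own number. Quantile normalisation left 84 in the interaction. Without clusters under the 50th percentile the share raised was 50.8%, the correlation of the SB effects 0.64 and the interaction lists 6. Array weights gave 2794 clusters in SB against control, 3076 in SB+Dox against SB, 1831 in Dox against control, 1935 in SB+Dox against control, 678 in the interaction, a share of 53.7% and a Myog interaction of -0.03. A minimum fold of 1.5 can only remove calls and left 683 in SB against control, 725 in SB+Dox against SB, 1099 in SB+Dox against Dox, 669 in Dox against control and 569 in SB+Dox against control, with a share of 36.6%. With unnamed and multi-gene clusters tested too, 876 passed in SB against control, 696 in SB+Dox against control and 6 in the interaction. A 2-fold minimum for SB-lowered clusters gave a share of 54.2%, and measuring on number 3 a median recovery of 0.65. Leaving out arrays leaves a group with fewer arrays. The ranges were 348 to 1790 for SB against control, 416 to 2521 for SB+Dox against SB, 902 to 2511 for SB+Dox against Dox, 406 to 1305 for Dox against control, 266 to 1351 for SB+Dox against control and 6 to 352 for the interaction. The share raised ran from 30.6% to 55.3%, the median recovery from 0.39 to 0.61 and the correlation from 0.45 to 0.61. Lists called ran from 8 to 16 in SB+Dox against SB, 6 to 15 in SB+Dox against Dox, 6 to 10 in Dox against control, 11 to 17 in SB+Dox against control and 8 to 17 in the interaction. The Myog interaction ran from -0.21 without SB replicate 1 to 0.43 without SB replicate 3, and Myod1 in Dox against control from -0.05 without control replicate 3 to 0.21 without control replicate 2. The share raised cannot be had on a single held-out array, nor the interaction from 6 arrays, and a linear-scale alternative was not needed for log2 values.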

Other observations

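Cth and Dhrs9 were among the highest folds in SB+Dox against SB. Cth, the cystathionine gamma-lyase gene, was 4.73-fold higher (log2 change 2.24, SE 0.40, adjusted p = 0.0036, limma) and Dhrs9, a retinol dehydrogenase gene, 5.31-fold higher (SE 0.35, adjusted p = 9.52e-04), on 3 of 3 arrays each. Nuclear respiratory chain genes had a mean of 0.15 in the same comparison, on all 3 arrays (camera adjusted p = 1.37e-04; adjusted p = 0.587 with an estimated correlation), with 1 of 29 raised and 0 lowered. In SB+Dox against Dox the malic enzyme gene Me1 was 1.8-fold higher and cyclin D1 (Ccnd1) 2.72-fold higher (adjusted p = 9.50e-04 and 2.00e-05, limma), again on 3 of 3 arrays.

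The test in this paragraph was chosen only after the result was seen. Of the sarcomere genes called lower in SB against control at any fold, 15 of 21 were raised by doxycycline, against 1 of 18 matrix genes chosen in the same way, and the shares differed with an exact two-sided Fisher p = 4.39e-05. Genes of a list are not independent, so this p may be too small, and the matrix gene raised, Thbs1, lost its call without SB+Dox replicate 3 (adjusted p = 0.0523, limma). Matrix genes were also lower with doxycycline without the inhibitor (12 of 37 lowered and 3 raised, or 17 and 6 over the list alone; mean -0.34 in Dox against control, camera adjusted p = 5.67e-05; adjusted p = 0.422 with an estimated correlation). Why the shares differed was not tested, and doxycycline cannot be separated from exogenous Myog here.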
